A study of Homo sapiens with 2 samples.

How the data were processed

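Chromatin immunoprecipitation with a rabbit antibody against HMGB2 was followed by sequencing in 1 library of RAS-induced senescent and 1 library of growing IMR90 cells, each prepared from 10 ng of precipitated DNA at day 2. Groups were taken from the cell condition in the labels, and no sample was left without a group. The submitters' processing notes name Bowtie 0.12.9, HOMER 1.0 and the genome build hg19, with no role or order. The peak calling settings, filters, treatment of duplicate reads, use of an input control and number of reads are not given in the sources used here.

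The authors deposited 2 lists of regions, and per the file headers each holds an identifier, a chromosome, a start and an end in bp. The values are base positions and carry no normalization, score, fold, p-value or read count. The names of the lists put senescent before growing, from which the direction (higher in senescent cells) was taken. The sources used here do not state it otherwise, and no value in the lists tests it. Whether positions count from 0 or from 1 is not stated, so a printed start could differ by 1 bp, and width was taken as end minus start. The lists report called regions and not signal, so a place without a region can be one where the signal missed the threshold of the authors. The depth of each library is unknown. The precision given is the counting error of regions, as exact (Clopper-Pearson) binomial 95% intervals for shares and exact Poisson 95% intervals for regions per Mb, with 3 counts behind the limit of a count of 0.

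Tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Overlap was at least 1 bp, and its chance level came from 10000 random placements of the broad regions on their own chromosomes. The overlap count was checked with bedtools, which also gave 100 broad regions. Regions per Mb used the hg19 chromosome lengths. Clustering was the number of regions with another within 10 kb, edge to edge, against 1000 placements (300 in the alternatives). On simulated data, 60 of 60 planted overlaps among 364 regions and 97 of 100 planted neighbours among 2792 regions were recovered, which checks the counting only. Of 200 random band lists with nothing planted, 10 were called. Their bands and the simulated hits were drawn evenly from all bands. Bands with a broad region over 500 bp held a median of 46 protein-coding genes, against 16 per band, so this rate does not cover hits that follow gene number.

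The planned results on position relative to genes, gene lists with regions in the gene body or within 5 kb, and sequence composition need an annotation or sequence of hg19, which was not used here, and were not run. The rule for named genes was to name every member of the fixed lists other than controls with a region within 5 kb, the genes of the 10 narrow and 10 broad regions with the highest score (or width), and the 10 genes with the most narrow regions. None of its parts could be applied as written. In its place, a join by chromosome band was chosen after seeing the data, and genes named in the text are members of the fixed lists in bands with or without regions. The lists were those of SASP secreted factors, NF-kB, C/EBP and IL-1 regulators, cell cycle and replication, HMGB, lamin and chromatin factors, arrest and tumour suppressor genes, RAS-ERK feedback and immediate early genes, interferon response, and fibroblast and matrix genes, with housekeeping, long neuronal and olfactory receptor genes as controls.

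For the join, regions were placed in hg19 bands, and protein-coding genes of a gene table of the assembly GRCh38.p14 were placed in the GRCh38 bands of the same name. No coordinates were converted. All 862 band names are shared by both builds, and 503 bands (58.4%) have the same length to within 100 kb. Every symbol of the lists was matched, and single results of some genes are not reported here. Each list was compared with 10000 random sets of bands matched on the number of protein-coding genes in 10 bins, and was called set apart when fewer than 5% of the sets held as many bands with a region. The same counts were made for the wide broad regions (over 500 bp), all broad regions, the first 279 narrow regions and all narrow regions. Dark bands were the 2 darkest Giemsa classes and light bands those without stain, and centromere, variable and stalk bands were left out, both of the regions and of the 1000 placements. Wide regions within 500 kb of each other were called a group. The division into wide regions, the band classes and the use of the deposited order were also chosen after seeing the data.

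The alternatives varied the merging distance (1 kb), the overlap (50% of the narrow region, or within 1 kb), the clustering distance (1 and 100 kb), the chromosomes included, the part of each list used, the random placement, and the matching of random bands. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, bedtools 2.31.1, and R 4.3.3 with circlize 0.4.16, from which the band tables came, and GenomeInfoDb 1.38.1.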

Results

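HMGB2, a high mobility group box protein that binds and bends DNA in chromatin, was mapped by chromatin immunoprecipitation and sequencing in IMR90 cells, which are human lung fibroblasts. The study had 2 libraries, 1 from cells made senescent with RAS and 1 from growing control cells, both taken at day 2 and cultured in 2% oxygen. RAS is an oncogene whose activity drives fibroblasts into senescence, a lasting arrest in which cells secrete cytokines, chemokines and proteases known as the senescence-associated secretory phenotype (SASP). The measurements analysed here were 2 lists of regions that the authors called in the senescent against the growing library, 1 of narrow and 1 of broad regions. That the regions are higher in senescent cells was read from the order of the conditions in the list names and is not stated otherwise in the sources used here. The opposite comparison was not analysed here. The lists gave positions in hg19 and no score, fold or read count, so the depth of each library is unknown and the size of the difference at a region cannot be given. With 1 library per condition, no difference had a replicate check, and the percentiles among random placements or random sets describe these lists only.

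The narrow list held 2792 regions, all of 264 bp, which covered 737 kb on 24 chromosomes, with only 1 region on chromosome Y. The broad list held 364 regions of 500 to 6140 bp, which covered 235 kb on 23 chromosomes. Of the broad regions, 311 had the smallest width of 500 bp and 53 were wider (14.6%). These 53 regions, called wide from here on, had a median width of 1048 bp and lay in 34 of the 862 chromosome bands.

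The first comparison asked where the HMGB2 regions called in senescent against growing cells lay relative to SASP genes, the loci named in the title of the study. Wide regions gathered in the chromosome bands of SASP genes. Of the 33 bands that hold the 50 genes of the SASP list, 11 held a wide region, against a median of 3 in random band sets with similar numbers of genes, and none of 10000 such sets held as many. These bands made up 4.91% of the hg19 length and held 21 of the 53 wide regions (39.6%). That share counts neighbouring wide regions singly, whereas the count of 11 bands was the same with wide regions within 500 kb counted once. The band join placed regions and genes in the same band by name, and a band spans up to several megabases, so it does not show at which gene a region lies. Among bands of the same length in both builds, 3 of 13 SASP bands held a wide region, and 320 of 10000 sets held as many.

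Band 4q13.3 holds the neutrophil-attracting chemokine genes CXCL1, CXCL2, CXCL3, CXCL5, CXCL6 and CXCL8 and the epidermal growth factor receptor ligand genes AREG and EREG. It held 4 wide regions between positions 74606793 and 74962673 of chromosome 4, with a summed width of 7370 bp. The widest of them, from 74606793 to 74610581, spanned 3788 bp and stood at place 3 of the broad list. Band 11q22.2 has 12 protein-coding genes, among them the matrix metalloproteinase genes MMP1, MMP3, MMP10, MMP12 and MMP13, whose products degrade the extracellular matrix. It held 4 wide regions within 48.3 kb of chromosome 11, from 102658722 to 102707064, with a summed width of 7332 bp.

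**Figure D1:**
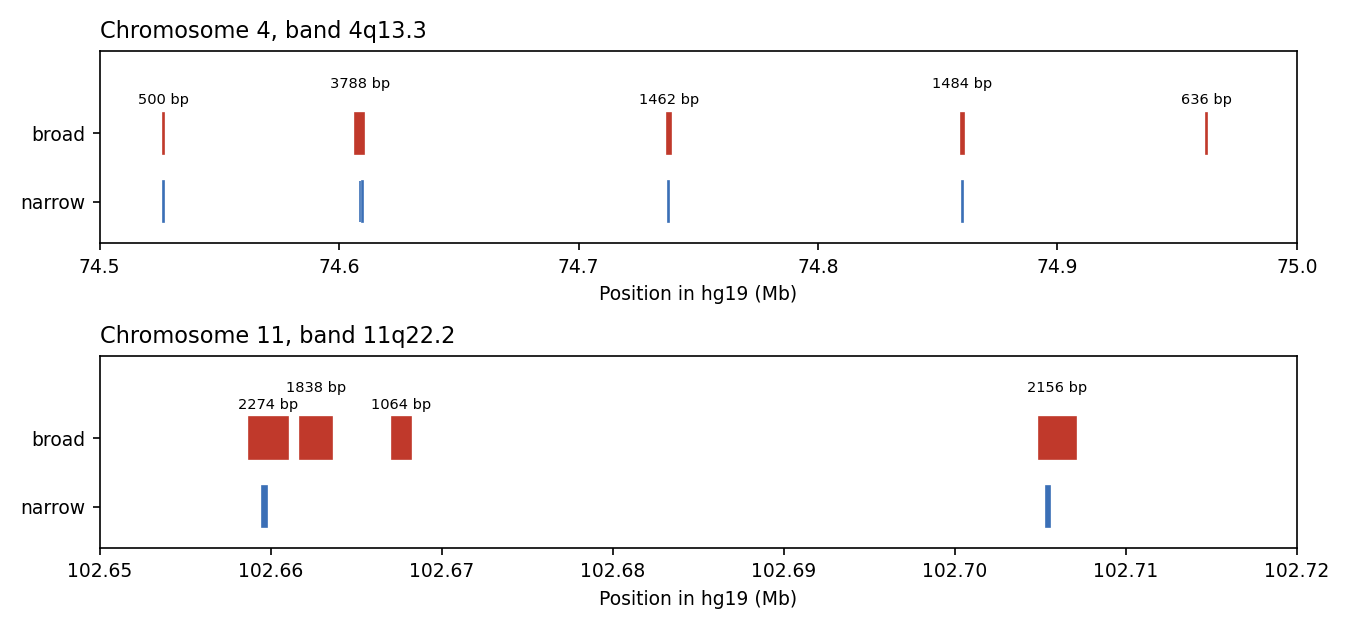
Broad regions (red, with widths in bp) and narrow regions (blue) along hg19 positions in Mb in band 4q13.3 of chromosome 4 and in band 11q22.2 of chromosome 11. Each panel holds 4 wide regions, of 636 to 3788 bp on chromosome 4 and of 1064 to 2274 bp on chromosome 11.

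Single SASP genes lay in other bands with wide regions. PLAU, the urokinase plasminogen activator, lies in 10q22.2, which held wide regions of 3544 and 2578 bp on chromosome 10 at 75675285 to 75678829 and 75671551 to 75674129. CSF3, a granulocyte growth factor, lies in 17q21.1, a band of 14 protein-coding genes with a wide region of 2226 bp at 38173682 to 38175908 of chromosome 17. LIF, an interleukin 6 family cytokine, lies in 22q12.2 with 2 wide regions, and STC1, a secreted glycoprotein hormone, lies in 8p21.2 with 3. PLAT, NRG1, MMP14, TIMP2 and the pair ICAM1 and ANGPTL4 lie in 8p11.21, 8p12, 14q11.2, 17q25.3 and 19p13.2, each with 1 wide region of 628 to 1108 bp. The length of 19p13.2 differs between the builds (7.0 Mb in hg19 and 5.7 Mb in GRCh38), so its pairing with ICAM1 and ANGPTL4 is uncertain. Of the 11 SASP bands with a wide region, only 3 had the same length in both builds to within 100 kb. The pairings in the others are uncertain too. In all, 23 of the 50 SASP genes lay in a band with a wide region.

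Another 12 SASP genes lay in bands with broad regions of 500 bp only. IL6, a central SASP cytokine, lies in 7p15.3, which held 3 of them, and CXCL10, CXCL11, VEGFA and HGF lie in bands with 1 each. The bands of the remaining 15 genes held no broad region, among them those of CCL2, CCL7, IGFBP3, IGFBP5, IGFBP7 and the interleukin 1 genes IL1A and IL1B. The widest region of the list, 6140 bp from 113586040 to 113592180 of chromosome 2, lay in 2q13. IL1A and IL1B were placed in the bordering band 2q14.1, and the lengths of both bands differ between the builds (4.2 and 3.5 Mb for 2q13 and 4.4 and 5.9 Mb for 2q14.1 in hg19 and GRCh38), so the join does not settle whether that region lies at these genes.

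The feedback and immediate early genes of the RAS-ERK pathway were the other list set apart. Of its 19 bands, 7 held a wide region, against a random median of 1, and 2 of 10000 random sets held as many. With only bands of the same length in both builds, 5 of 13 held one (3 sets), and the pairings in other bands are uncertain. Without 11p15.5, the band of HRAS, the RAS gene of this list, 6 of 18 bands held one (4 sets). The call was lost with the first 279 narrow regions (7 of 19 bands, 3242 sets) and with all narrow regions (17 of 19, 7171 sets), as was that of the SASP list with all narrow regions (33 of 33, 741 sets). IER3, an early response gene, lies in 6p21.33, where the region listed first in the broad list spanned 3858 bp from 30708362 to 30712220 of chromosome 6. DUSP6 and DUSP4, phosphatases that act on MAP kinases, lie in 12q21.33 with 2 wide regions and in 8p12 with 1. Band 8p12 is also that of NRG1, so its 1 wide region was counted for both the SASP and the RAS-ERK list. PHLDA1 lies in 12q21.2 with 2 wide regions, and SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, FOSB, a subunit of the AP-1 transcription factor, and HRAS lie in 13q31.1, 19q13.32 and 11p15.5 with 1 each. Together, 17 of the 34 bands with a wide region held a gene of the SASP or RAS-ERK list, and 5 of the 10 widest regions lay in such bands.

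The other lists were not set apart by the number of bands with a wide region against random bands matched on gene number. By the number of wide regions, the long neuronal genes, a control list, held 5 of 53 against a random median of 1, and 218 of 10000 sets held as many. With random bands matched on length or not matched, the same counts were set apart for the arrest genes (63 and 53 of 10000 sets as high) and the olfactory receptor genes, a control list (300 and 261 sets), and, matched on length, for the NF-kB list (457 sets). For the arrest and tumour suppressor genes, 4 of 18 bands held a wide region, among them those of CDKN2C and RBL2, and 656 of 10000 random sets held as many. With all broad regions, 13 of these 18 bands held a region, and 94 sets held as many. Of the 4 bands with a wide region, only 1 had the same length in both builds, so the other pairings are uncertain. The NF-kB, C/EBP and IL-1 regulators had 3 of 23 bands with a wide region (2216 sets as high), those of the transcription factors CEBPB, JUNB and RELB. The band of JUNB, 19p13.13, is 0.1 Mb long in hg19 and 1.2 Mb in GRCh38, so that pairing is uncertain. The cell cycle and replication genes had 4 of 38 (3391 sets), those of AURKB, BIRC5, BUB1 and CCNE1. Only 1 of these 4 bands had the same length in both builds, so the other pairings are uncertain. The band of BUB1, 2q13, is 4.2 Mb long in hg19 and 3.5 Mb in GRCh38, so that pairing is uncertain. Its widest region is the one that the join could not place relative to IL1A and IL1B. For the HMGB, lamin and chromatin factors it was 1 of 20 (8984 sets), for the interferon response 2 of 16 (3330 sets), and for fibroblast and matrix genes 3 of 26 (2918 sets). Among the control lists, housekeeping genes had 3 of 20 bands (2557 sets), long neuronal genes 2 of 20 (1746 sets) and olfactory receptor genes 5 of 41 (4540 sets). The long neuronal genes, a control list, were set apart for the first 279 narrow regions (10 of 20 bands, 164 sets) and for all narrow regions (20 of 20 bands, 413 sets). The values matched on gene number belong to 44 comparisons of 11 lists with 4 sets of regions, in each of which both bands and regions were counted. Differences between lists were not tested.

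**Figure D2:**
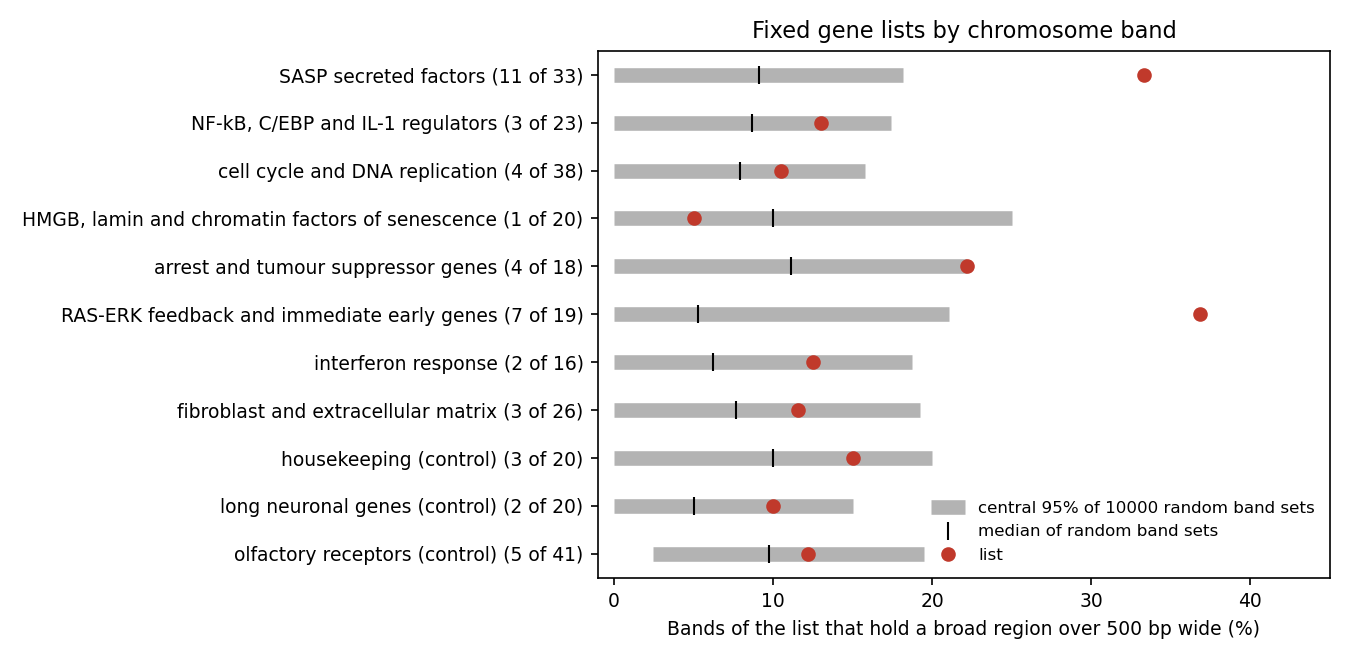
Percent of the bands of each fixed gene list that held a wide region (red points), with the central 95% (grey bars) and median (black ticks) of 10000 random band sets matched on gene number. The SASP list stands at 11 of 33 bands and the RAS-ERK list at 7 of 19, both above the grey bars.

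The second comparison asked whether the narrow and broad lists marked the same places. Both lists were called on the same 2 libraries, so an overlap above random placement was likely in advance and is no independent agreement. Of the 364 broad regions, 100 held a narrow region (27.5%, exact binomial 95% interval 22.9 to 32.4), whereas random placement of the broad regions gave a median of 0 and at most 5 in 10000 placements. The share was 39.6% among wide regions (21 of 53, 26.5 to 54.0) and 25.4% among those of 500 bp (79 of 311, 20.7 to 30.6). The wide regions with a narrow region included those of 6140 bp in 2q13, 3858 bp in 6p21.33 and 3788 bp in 4q13.3, the last with 2 narrow regions. Neither wide region of 10q22.2 nor the region of 3436 bp in 1q21.3 held one. Only 101 of the 2792 narrow regions (3.62%) lay in a broad region, and 70 of these were among the 279 listed first (25.1%). None of the last 280 did, which allows a share of up to 1.07%. Intervals here and elsewhere cover counting error only, and the meaning of the order of the lists is not given in the sources used here.

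**Figure D3:**
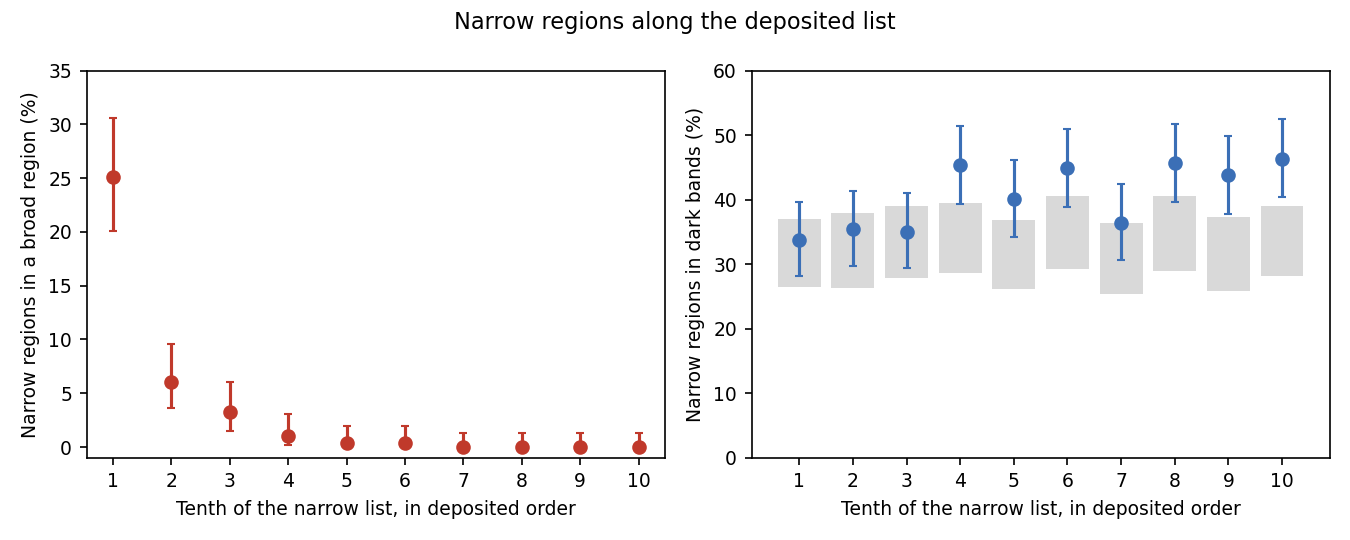
Narrow regions along the deposited order in 10 consecutive parts, as the percent that lay in a broad region (left) and the percent in dark chromosome bands (right). Points carry exact binomial 95% intervals, and grey bars are the central 95% of 1000 random placements for each part; the share in a broad region falls from 25.1% to 0.

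The third comparison asked how the regions were spread over chromosomes and bands. Chromosome 6 had the most narrow regions per Mb, 1.13 (exact Poisson 95% interval 0.980 to 1.30), against 0.902 over the genome, and chromosome 22 had 0.331 (0.193 to 0.531). The interval of chromosome 6 overlaps those of most other chromosomes, among them 4 (1.10 per Mb), X (1.09), 3 (1.08) and 21 (1.04). Their order is thus not settled. Full lengths were used, with no assembly gaps left out and with chromosome Y in the genome value. Broad regions were densest on chromosome 19, at 0.254 per Mb (0.142 to 0.418), against 0.118 over the genome, but with regions within 1 kb merged chromosome 20 was the densest, at 0.238 per Mb. Chromosome 19 also held 7 of the 53 wide regions, and chromosomes 3, 5, 7, 9, 15, 18, X and Y held none.

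**Figure D4:**
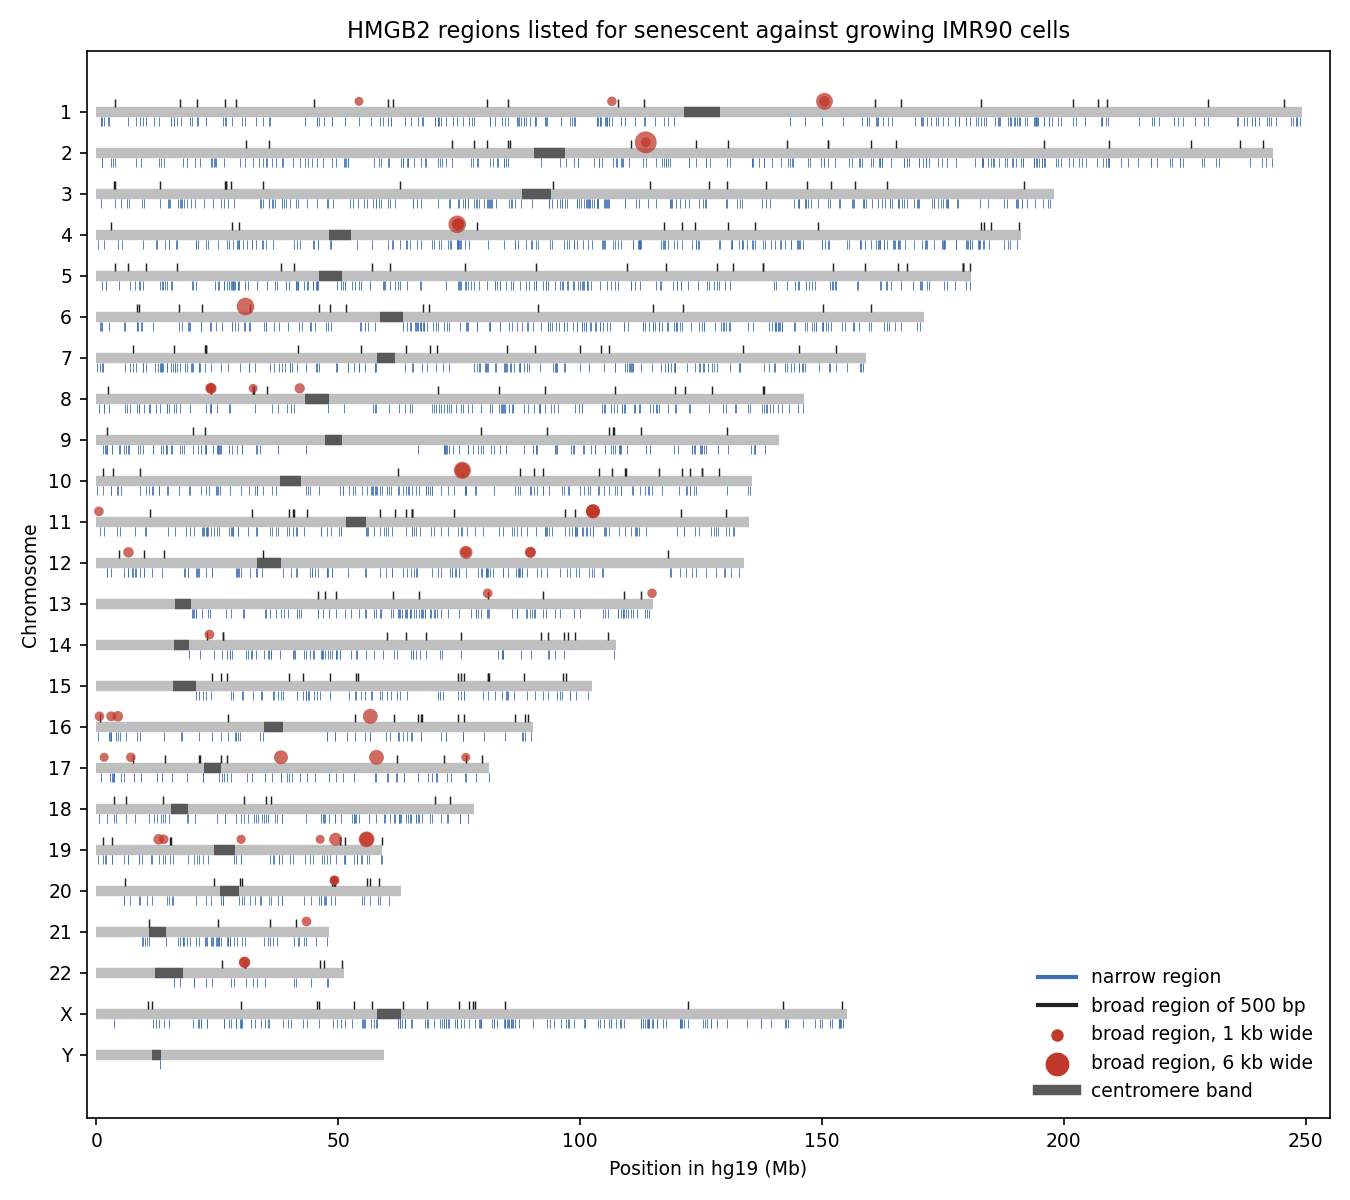
Positions of narrow regions (blue ticks), broad regions of 500 bp (black ticks) and wide regions (red circles, with size growing with width) along the hg19 chromosomes in Mb, with centromere bands in dark grey. Wide regions lie on 16 chromosomes, 7 of them on chromosome 19, and narrow regions on all 24, with only 1 on chromosome Y.

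Narrow regions lay in dark bands, and wide regions in light bands, more often than random placements, and the difference between the lists was not tested. Dark Giemsa bands, which are poor in genes and rich in A and T, held 1116 of 2745 narrow regions (40.7%, 38.8 to 42.5), against 31.0 to 34.5% in random placements. Light bands, which are richer in genes, held 35 of 52 wide regions (67.3%, 52.9 to 79.7), against 32.7 to 59.7% in random placements, and 2 of 1000 placements were as high. Dark bands held 9 of 52 wide regions (17.3%), inside the random range of 15.4 to 38.5%. Light bands held 40.9% of narrow regions, below the random range of 43.8 to 47.4%. All broad regions lay in light bands at 48.6%, inside the random range of 41.4 to 51.7%. With gap-like bands left out, the dark share of narrow regions was 33.7% in the first 279 listed (93 of 276) and 46.4% in the last 280 (127 of 274). It did not rise steadily between them, with 36.4% in the 7th of 10 parts, and was 37.9% over the first 1396, above the random range of 30.2 to 34.8%.

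Wide regions also lay close to each other. Within 500 kb of another lay 28 of the 53, against a random median of 2 and a highest value of 9 in 1000 placements. They formed 11 groups, among them those in 4q13.3, 11q22.2, 8p21.2 and 20q13.13, the last the band of CEBPB. With wide regions within 5 kb of each other joined, the 53 became 44 loci, and 8 of these loci took up 17 regions. Part of the closeness can thus lie between neighbouring calls of the same stretch, which random placement of single regions does not take into account. Of all broad regions, 39 (10.7%) lay within 10 kb of another, and none of 1000 placements was as high. Of the narrow regions, 64 (2.29%) lay within 10 kb of another, inside the random range of 34 to 74, but 614 (22.0%) lay within 100 kb, above the random range of 429 to 530. Taken separately, the first 1396 narrow regions had 142 within 100 kb of another, inside their random range of 98 to 153, and the last 1396 had 192, above theirs of 102 to 158.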

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

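Alternatives on the part of each list used, the placement outside gap-like bands, the band classes and the lists by band were chosen after the result was seen. The SASP list stayed set apart, including 9 of 31 bands without 4q13.3 and 11q22.2, 10 of 32 without 19p13.2 and 19p13.13, and 3 of 13 of the same length in both builds (320 of 10000 sets as high), except with all narrow regions, which lay in 33 of 33 bands (741 sets). The RAS-ERK list stayed set apart except with the first 279 narrow regions (7 of 19 bands, 3242 sets) and all narrow regions (17 of 19, 7171 sets). Of the 9 other lists, the arrest, NF-kB, long neuronal and olfactory receptor lists became set apart, in 9 comparisons in all. The overlap of broad with narrow regions stayed above random placements, at 27.2 to 39.6%, except with the last 1396 narrow regions, which lay in 0.275% of the broad regions, not above the random range. Counts fell to 1396 narrow and 182 broad regions in the first part of each list, by construction, and to 53 broad regions over the smallest width. In that first part, the densest chromosome for narrow regions was 21, at 0.644 per Mb. Clustering of narrow regions passed the random range only within 100 kb, at 22.0% against 15.2 to 19.0%, or 16.1 to 20.3% with placement outside gap-like bands. The dark share of narrow regions was inside the random range in the first 279 listed, at 33.7% against 26.8 to 37.0%. Where no construction is named, the cause was not tested. The planned stricter choice by score or width gave no value, because no score is given and 311 of 364 broad and all narrow regions tie in width. The alternatives on position relative to genes, gene windows and sequence composition were not run. No paired analysis was possible because each group has 1 library and the results come from no test between samples. The unknown depth limits what a missing region can show.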

Other observations

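The tests on gene-rich bands, on an even background and on the RAS construct were chosen after the result was seen, whereas those on ribosomal protein genes and on late-replicating DNA were written down before their results were seen. Of the 34 bands with a wide region, 9 held no gene of the fixed lists other than controls. Band 19q13.42 held wide regions of 2956 and 2264 bp on chromosome 19, at 55875292 to 55878248 and 55879645 to 55881909. Band 1q21.3 held regions of 3436 and 1084 bp on chromosome 1, at 150539847 to 150543283 and 150544166 to 150545250. Band 17q23.1, with 9 protein-coding genes, held a region of 2570 bp at 57919408 to 57921978 of chromosome 17. Band 12p13.31, which holds the housekeeping gene GAPDH, held a wide region of 1060 bp at 6647421 to 6648481 of chromosome 12.

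Wide regions gathered in the bands of SASP and RAS-ERK genes. Gene number alone cannot be the whole source for the SASP list. Of 10000 random band sets matched on gene number, 0 held as many bands and the highest held 9, though 320 did among bands of the same length in both builds. This restates the comparison that gave the pattern and is no separate evidence, and the RAS-ERK list was not part of it. Signal that follows transcription stays open: of the 75 bands of ribosomal protein genes 9.33% held a wide region (3.84 to 18.3; 4538 of 10000 sets as high), below the 33.3% of SASP bands, which went against it by the bound written beforehand. That bound was wrong by design, because the regions are differences between senescent and growing cells and signal at genes transcribed highly in both would cancel. A gain of HMGB2 in the bands of SASP and RAS-ERK genes in senescent cells may be an explanation, if the lists hold regions higher in senescent cells. It is an untested hypothesis found on the same data, and the join does not show at which genes such a gain would lie. Open chromatin that is easier to precipitate with any antibody also stays open, untested, because an input or another antibody was not analysed here.

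Narrow regions lay in dark bands more often than random placements, in the first 1396 listed (37.9%) as in the last 1396. An even background cannot be the whole source, at 43.4% of the last 1396 against 30.7 to 35.4% in random placements, but this restates the pattern and leaves an uneven background open. Late-replicating DNA, which a growing culture with cells in S phase holds in a lower proportion than an arrested one, may contribute, under the same reading of the direction. Among those 1396 regions the darkest bands had 1.70 times the regions per Mb of light bands (0.696 against 0.409), but the 2 lighter grey classes, at 0.410 (Poisson 95% interval 0.329 to 0.505) and 0.395 (0.336 to 0.461), had intervals that overlap that of light bands (0.375 to 0.446), and the lower of them was below light bands, so the test did not decide. The excess in the darkest bands is part of the pattern itself. A result against late replication was therefore unlikely in advance. Base composition stays open, since it was not analysed here, and senescence itself stays open, untested.

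A wide region of 814 bp lay in 11p15.5, the band of HRAS, at 532297 to 533111 of chromosome 11. DNA of the introduced RAS construct could give such a region. The band has 85 protein-coding genes, and which RAS gene was introduced is not given in the sources used here. The position of the region was not compared with those of genes. The number of genes in the band therefore cannot decide between DNA of the construct and HMGB2 at HRAS or elsewhere in the band.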
